A study of Mus musculus with 8 samples.

How the data were processed

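Liver RNA of hypophysectomized male CD-1 mice was measured in 8 libraries that form 4 groups, untreated mice (Hypox) and mice 30, 90 or 240 min after 1 intraperitoneal injection of recombinant rat growth hormone (GH) at 125 ng per g of body weight. Per the labels, the pituitary was removed at 7 weeks of age and the mice were 11 weeks old. The labels describe the controls as untreated in the study design and as given vehicle in the treatment protocol. Each group holds 2 biological replicates, each a pool of RNA from several animals, so that the spread measured here is the spread between pools. Per the labels, total RNA was extracted with Trizol, ribosomal RNA was partly depleted, and strand-specific libraries were made with the NEBNext Ultra Directional kit.

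The authors deposited 1 table of 24197 mouse genes with coordinates in build mm9. Per the file headers, it holds the mean FPKM (reads normalized to exon length and to mapped reads) of the 2 replicates of a group over the gene body. The authors also deposited an intronic signal, the mean read density over introns alone, in the same unit. For each time against Hypox the authors' deposited table gives an expression ratio and an adjusted p-value, once for the gene body and once for introns. Per the submitters' processing notes, TopHat2, featureCounts and edgeR were used, with no versions given. How reads were assigned to exons and introns, whether counting used the strand, and how the p-values were adjusted is not given in the sources used here. Genes that overlap, and members of gene families with near-identical sequence such as Mup, Cyp, Ces and Saa genes, may therefore share reads, and their values are uncertain.

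No value per library was used directly, because the table holds group means. Whole reads per library were instead recovered from those means by arithmetic. A mean FPKM, written with 10 decimals, is a sum of 2 whole numbers of reads, each divided by its library's total and by the gene's length. The 8 library totals and the gene lengths were solved from the steps between values, with a relative tolerance of 1e-07. Of 18359 genes with a gene body value above 0, 18357 (99.99%) gave whole reads in all libraries, and Kcnq1ot1 and Ttn did not. A further 5838 genes are listed at 0 in every group. With each total moved by 1000 reads, 6 of 1000 genes gave whole reads, against 1000 of 1000 with the totals used. Among genes at a single location, 14441 of 14441 (100.0%) with an intronic value gave whole intronic reads, and the exonic and intronic lengths added up to the gene's span for 9490 of 9519 genes (99.7%) with 50 or more reads of each kind. For 49 genes more than 1 length fitted, and the one with the smallest difference between libraries was taken. On simulated data, 1499 of 1500 genes were recovered exactly. The arithmetic does not tell which pool is number 1 or 2, so a library is called the deeper or the shallower of its group. The total behind the FPKM values is taken as the number of mapped reads.

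Exonic and intronic reads were tested separately with limma. Reads were divided by the library's mapped reads to give CPM, scaled by a median-of-ratios factor from genes with a mean of at least 50 reads (0.916 to 1.05 for exonic reads), and log2(CPM + 0.1) was fitted with limma's trended variance over all 8 libraries, with the group as the only term. Genes with at least 10 reads in at least 2 libraries were tested, which left 13169 genes for exonic and 10164 for intronic reads. The 8 libraries in 4 groups leave 4 residual degrees of freedom, and limma added 6.45 prior degrees of freedom. Each of the 6 pairs of groups was compared, two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene is called higher or lower at an adjusted p under 0.05. A fold change on the log2(CPM + 0.1) scale understates the change of genes with few reads. The value after ± is limma's standard error of a log2 fold change between groups of 2 libraries. The median standard error was 0.20.

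Gene lists for 22 pathways and 13 cell types, the comparisons, the kinetic classes and the rule for named genes were fixed before the data were examined. Each list was tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, whose directional p asks whether a list moves one way and does not compare it with other genes. Members called were counted over all genes and adjusted over the list alone. The named genes are, at each time against Hypox, up to 10 largest rises and 10 largest falls with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 2 CPM and both treated libraries beyond both Hypox libraries; the 3 largest of each direction between times by the same rule; for each list and time up to 4 called members with the smallest p, or 1 member if none was called; the 3 largest non-coding genes of each direction; and, at every time, Igf1, Igfals, Socs2, Cish, Socs3, Bcl6, Onecut1, Cux2, Ghr, Fos, Myc and Alb. Genes outside the rule are named as chosen after their values were seen. Noc2l, Ighm and Trbc2, each in 1 of the lists, are not analysed here.

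The plan was edgeR's test on whole-number counts as the submitters' processing notes name it, and for a table of group means the authors' values with no test of its own. Because whole reads could be recovered, limma was used in place of that, and this choice and the pseudocount of 0.1 were made after the data were seen. The authors' deposited calls are given beside those of limma. Alternatives were other scaling, limma-voom, other filters on low reads, a pseudocount of 1, the 2 groups of a comparison fitted alone, a fold threshold, and leaving out each library in turn. The pools of each group differed by more than counting noise, with a chi-square per gene of 13.5 in Hypox, 28.0 at 30 min, 8.69 at 90 min and 16.1 at 240 min, so that no library was a copy of another. By the labels, 1 of the Hypox pools belongs to another library series than the other 7 libraries. It cannot be tied to the deeper or the shallower library, so the series could not be fitted. The other Hypox pool is of the same series as all treated libraries, so that 1 of the fits with a Hypox library left out lies within that series, and a call against Hypox kept in both of these fits does not rest on the series.

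The test was checked on reads simulated for 240 min against Hypox over 12932 genes. Every simulated gene had the same spread of 15% between libraries, so the shares below do not carry over to genes with a larger spread. It called 14.9% of 67 genes changed 1.5-fold, 77.6% of 67 genes changed 2-fold and 100% of 66 genes changed 4-fold, and 3 of its 131 calls were unchanged genes. In the same comparison camera gave a p under 0.05 for 8 of 200 random lists over 13169 genes. The simulated genes varied independently of one another, so this check does not cover lists whose members vary together. In the real data the estimated correlation was, for example, 0.267 for ribosome biogenesis and 0.527 for male-biased genes. It was 0.00665 for circadian clock genes and -0.0155 for endoplasmic reticulum stress and ATF4 targets. With an estimated correlation camera also uses the 4 residual degrees of freedom, fewer than at the preset one. Lists estimated below the preset 0.01 lost calls as well, so a lost call alone does not show that members vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The reference genome was not used here.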

Results

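Liver transcripts were measured in hypophysectomized male mice of the outbred CD-1 strain before and after a single pulse of growth hormone (GH). Hypophysectomy removes the pituitary, the source of circulating GH, so that the time course follows the liver from a state without its own GH pulses to 30, 90 and 240 min after one pulse. GH acts in hepatocytes through its receptor, the kinase JAK2 and the transcription factor STAT5b. Because total RNA with partial depletion of ribosomal RNA was sequenced, reads in introns, which come largely from unspliced transcripts, were measured beside reads in exons. Each of the 4 groups, Hypox and Hypox with GH for 30, 90 or 240 min, held 2 libraries, each from a pool of livers. Every time was compared with the same Hypox group, and no time had a control group of its own. A change against Hypox therefore cannot be told apart from an effect of injection, handling or time of day.

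The Hypox libraries held 34452570 and 32802312 mapped reads. The libraries held 27002584 and 20584956 mapped reads at 30 min, 32083366 and 15935303 at 90 min, and 25584732 and 21382154 at 240 min. Exonic reads of genes made up 28.9% to 31.6% of the mapped reads and intronic reads 11.2% to 13.1%, and 11632 to 12986 genes had 10 or more exonic reads in a library. The first principal component of the exonic values took 32.5% of the variance and set both 240 min libraries, at 33.1 and 40.3, apart from the other 6, which lay between -23.0 and -0.962. Across genes, Pearson's r was 0.979 to 0.984 between the libraries of a group and 0.958 to 0.982 between groups, where genes are not independent replicates. The shallower 30 min library stood apart in ribosomal RNA reads, with 19500 CPM of Rn45s before scaling against 6300 to 11900 CPM in the other 7, and in reads at Lars2, which were looked at after the values were seen. Male-biased liver genes were more abundant in the shallower than in the deeper library, with a median log2 difference of 0.57 in Hypox and 1.01 at 30 min.

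The first comparison asked which transcripts responded within 30 min. The transcription factor gene Myc, which drives growth and ribosome synthesis, rose 9.83-fold (log2 fold change 3.30 ± 0.33, adjusted p = 0.0052), from 0.632 and 1.32 CPM in the Hypox libraries to 8.64 and 11.4 CPM. Phlda1, a pleckstrin homology domain gene of the MAPK feedback list, rose 6.85-fold (2.78 ± 0.17, adjusted p = 0.000114). Onecut1, which encodes the liver transcription factor HNF6 and is a known GH target, rose 3.77-fold (1.91 ± 0.21, adjusted p = 0.00828). The Wnt receptor genes Fzd7 (1.67 ± 0.23, adjusted p = 0.0307) and, chosen after its values were seen, Fzd4 (1.00 ± 0.12, adjusted p = 0.0171) and the acetoacetyl-CoA synthetase gene Aacs (1.66 ± 0.24, adjusted p = 0.0442) also rose. The carboxylesterase gene Ces2b went from 2 and 4 reads to 30 and 60 (adjusted p = 0.0171). The genes that fell were Icam1, which encodes a leukocyte adhesion molecule, by 1.38 ± 0.14 on the log2 scale (adjusted p = 0.0052), and the chemokine gene Ccl2, by 2.12 ± 0.28 (adjusted p = 0.0247). The STAT5 feedback genes Cish and Socs2 had log2 fold changes of 2.74 ± 0.42 and 2.68 ± 0.57 without passing limma's test (adjusted p = 0.0667 and 0.221). Igf1, the main mediator of GH in growth, did not pass either, at 0.88 ± 0.27 (adjusted p = 0.494). By the authors' deposited adjusted p, Cish (7.44-fold, 5.49e-07) and Socs2 (9.01-fold, 7.04e-06) were called higher at 30 min, and Igf1 was not (0.141). In mm9, Myc lies on chromosome 15 from 61816896 to 61821916, Phlda1 on chromosome 10 from 110943342 to 110945705, and Onecut1 on chromosome 9 from 74709728 to 74737454. In all, limma called 7 genes higher and 2 lower of 13169, each with both treated libraries beyond both Hypox libraries, a separation that 38.4% of all genes showed against 33.3% by chance. In the authors' deposited table, higher genes numbered 46 and lower genes 59, and the 9 genes called here were among them. Without the deeper Hypox library 1 gene was called higher and 0 lower, without the shallower Hypox library 7 and 4, without the deeper 30 min library 30 and 8, and without the shallower 30 min library 4 and 2. Phlda1 was called in each case, whereas Myc, Onecut1 and Icam1 were lost without the deeper Hypox library (adjusted p = 0.0537, 0.0888 and 0.0888). Fzd4, Fzd7, Aacs, Ccl2 and Ces2b were lost without that library as well (adjusted p = 0.157, 0.305, 0.0584, 0.284 and 0.157). Without the shallower Hypox library the adjusted p was 0.0823 for Fzd4, 0.0914 for Fzd7, 0.123 for Aacs and 0.115 for Ccl2. Without the shallower 30 min library it was 0.133, 0.0844 and 0.155 for Fzd4, Fzd7 and Aacs. With the groups fitted alone, Onecut1 (adjusted p = 0.0716), Fzd4 (0.0638), Fzd7 (0.132), Aacs (0.182), Ccl2 (0.0895) and Ces2b (0.138) were lost. Ces2b was also lost with limma-voom (0.371) and a pseudocount of 1 (0.172).

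Chemokines and other targets of NF-kB, a driver of inflammatory transcription, were mostly lower at 30 min. Icam1 and Ccl2 fell among 15 tested members, 10 were lower adjusted over the list alone, and the median log2 fold change was -1.15 (camera adjusted p = 4.07e-16). That call was lost with the correlation estimated from the data (adjusted p = 0.0911 with an estimated correlation). Fry did not call the list either (fry adjusted p = 0.0593). The 4 tested neutrophil markers moved with this list, with a camera adjusted p of 0.0171 (adjusted p = 0.943 with an estimated correlation), and red blood cell markers went the other way (0.018, adjusted p = 0.943 with an estimated correlation). Of 15 tested GH and STAT5 target and feedback genes 1 rose, Onecut1, 7 were higher adjusted over the list alone, and none was lower (camera adjusted p = 5.55e-06, adjusted p = 0.266 with an estimated correlation). Camera called 14 of the 22 pathway lists at the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.0911. Fry called 0 of the 22. Across the pathway lists 3 members were called higher and 2 lower. Those counts were 1 and 0 without the deeper Hypox library, 6 and 2 without the shallower Hypox library, 12 and 5 without the deeper 30 min library, and 3 and 2 without the shallower 30 min library.

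**Figure D1:**
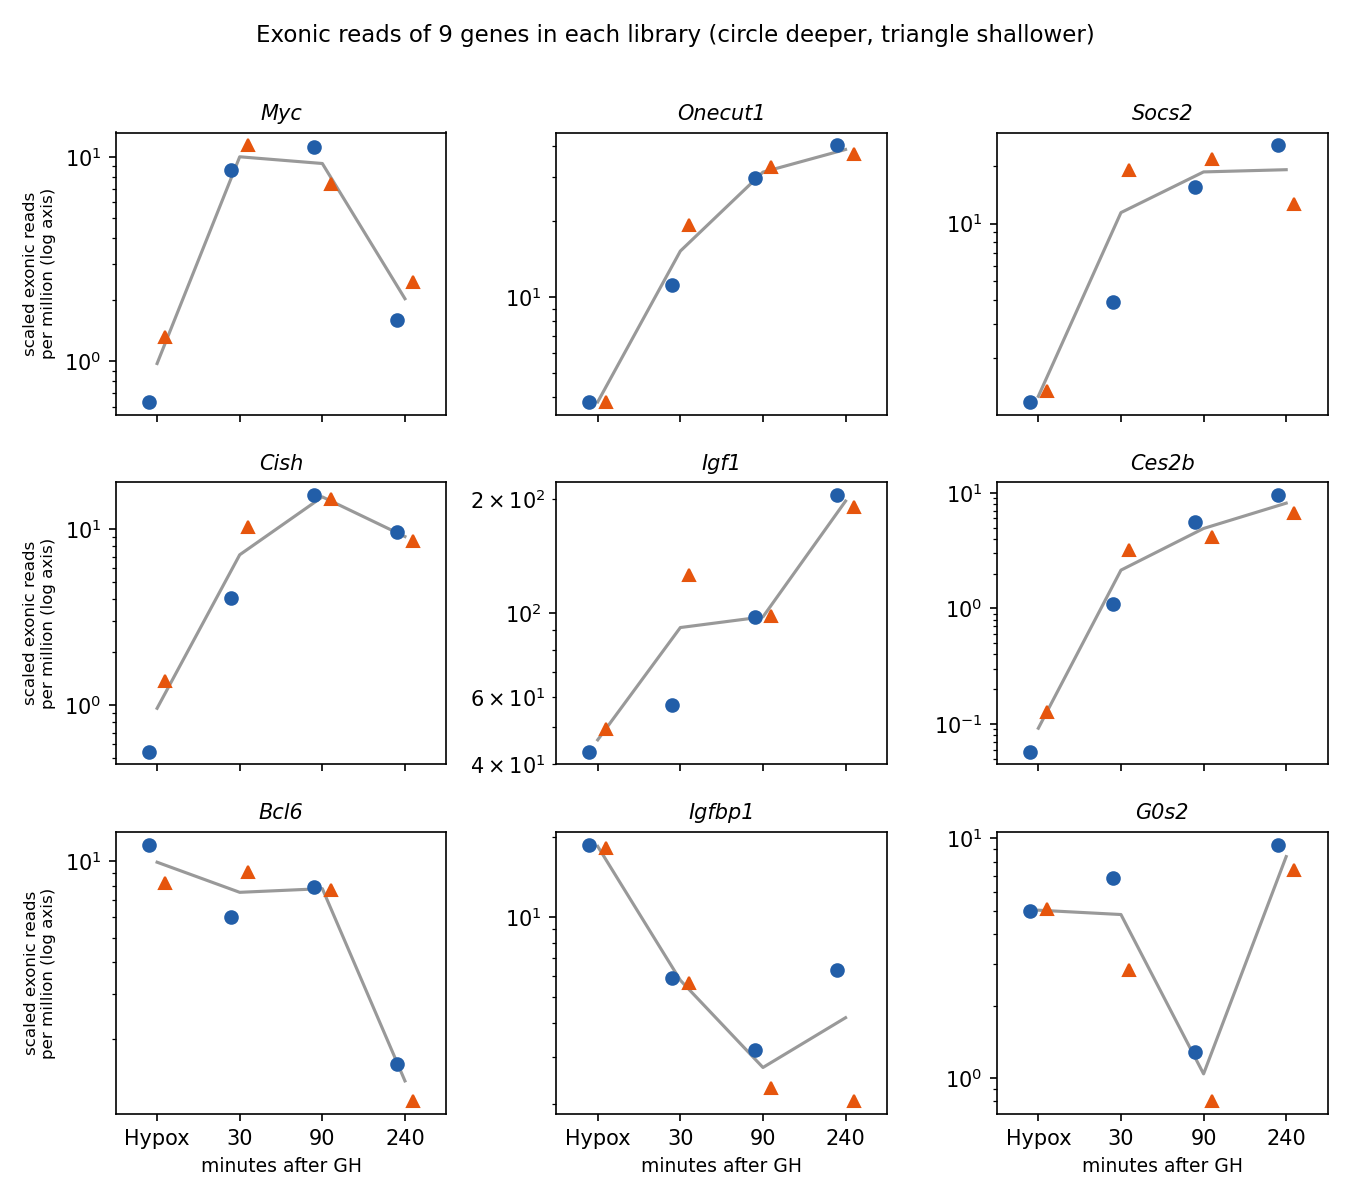
Scaled exonic CPM (vertical log axis) of 9 genes in Hypox livers and 30, 90 and 240 min after GH (horizontal axis), with a circle for the deeper and a triangle for the shallower library of each group and a grey line through the group means. Myc stood at 8.64 and 11.4 CPM at 30 min and at 1.6 and 2.45 CPM at 240 min, while Igf1 reached 205 and 190 CPM at 240 min from 43.1 and 49.5 CPM in Hypox.

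By 90 min Cish, Socs2 and Socs1, feedback inhibitors of GH signalling, had risen, while Socs3 was at 0.55 ± 0.27 (adjusted p = 0.562). Cish rose 15.7-fold (3.98 ± 0.42, adjusted p = 0.00333), Socs2 13.5-fold (3.75 ± 0.57, adjusted p = 0.0157), and Socs1, another inhibitor of JAK kinases, from 0.46 and 0.566 CPM to 6.98 and 2.77 CPM (2.88 ± 0.45, adjusted p = 0.0195). Onecut1 was 8.01-fold higher (adjusted p = 0.000209), Phlda1 10.2-fold (adjusted p = 1.71e-05), and Nrep, a gene first described in neurons, from 1.44 and 0.786 CPM to 13.4 and 14.5 CPM (3.59 ± 0.35, adjusted p = 0.00279). Myc was still higher (3.18 ± 0.33, adjusted p = 0.00333). Arid5a, an RNA-binding protein gene, and Sybu rose by 2.82 ± 0.34 and 2.63 ± 0.30 (adjusted p = 0.00923 and 0.00681). Igfbp1, an IGF-binding protein that insulin represses, was 6.64-fold lower (-2.73 ± 0.39, adjusted p = 0.0131), from 18.7 and 18.1 CPM to 3.18 and 2.28 CPM. G0s2, an inhibitor of the triglyceride lipase ATGL, fell by 2.20 ± 0.35 (adjusted p = 0.0208). The glycogen-associated genes Ppp1r3c and Stbd1 fell by 1.37 ± 0.26 and 1.09 ± 0.13 (adjusted p = 0.0477 and 0.00923). Cish lies on chromosome 9 from 107199020 to 107204292 and Igfbp1 on chromosome 11 from 7097790 to 7102549 in mm9. Igf1 (1.08 ± 0.27, adjusted p = 0.137) and Igfals, which encodes its serum carrier subunit (1.12 ± 0.23, adjusted p = 0.0656), did not pass limma's test. Both were called higher by the authors' deposited adjusted p (1.34e-09 and 3.09e-07). Limma called 83 genes higher and 24 lower, all with both treated libraries beyond both Hypox libraries, which held for 41.4% of all genes against 33.3% by chance. At 2-fold or more 55 were higher and 12 lower. The authors' deposited table held 221 higher and 166 lower genes, with 106 of the 107 genes called here in the same direction and 0 in the opposite one. The counts were 11 higher and 0 lower without the deeper Hypox library, 18 and 5 without the shallower Hypox library, 12 and 3 without the deeper 90 min library, and 8 and 4 without the shallower 90 min library. Of the 40 named calls, 7 were kept with each of these libraries left out, namely Aacs, Ces2b, Cish, Myc, Nrep, Onecut1 and Phlda1. Igfbp1 was lost in all 4 cases (adjusted p = 0.0707 to 0.152), as were Socs2 (0.0789 to 0.169) and G0s2 (0.0707 to 0.214). Both Socs2 (0.0711) and G0s2 (0.0859) were lost with limma-voom, where Ppp1r3c was lost as well (0.0686). Socs1 was kept only without the shallower 90 min library (adjusted p = 0.0403), Arid5a only without the deeper Hypox library (0.0365) and Stbd1 only without the shallower Hypox library (0.0448). Sybu was lost without the deeper and the shallower 90 min library (0.0583 and 0.0742), and Ppp1r3c in all 4 cases (0.121 to 0.4). With the Hypox and 90 min groups fitted alone, 54 genes were lower.

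Several GH and STAT5 target and feedback genes rose at 90 min. Of 15 tested, 6 rose and 0 fell (8 and 0 adjusted over the list alone), among them Pim3 (1.25 ± 0.18, adjusted p = 0.0135), and the median log2 fold change was 1.08 (camera adjusted p = 3.89e-11, adjusted p = 0.196 with an estimated correlation). Ribosome biogenesis genes were higher, with Nop58, a box C/D snoRNP protein (1.11 ± 0.16, adjusted p = 0.0131), and Rrs1 called of 29 tested and 9 adjusted over the list alone (camera adjusted p = 6.38e-10, adjusted p = 0.357 with an estimated correlation). Heat shock genes had 0 called of 12 at limma's adjusted p and 5 higher adjusted over the list alone (camera adjusted p = 3.63e-06, adjusted p = 0.357 with an estimated correlation). Of 20 liver transcription factors, the pioneer factor genes Foxa1 (1.61 ± 0.23, adjusted p = 0.0132) and Foxa2 (adjusted p = 0.0477) rose and Cebpb fell by 1.07 ± 0.19 (adjusted p = 0.0387), with 2 higher and 7 lower adjusted over the list alone. Female-biased genes included the rises of Fmo2, Acot3 and Slc16a5 among 36 tested (4 higher and 0 lower adjusted over the list alone). Of 26 male-biased genes Ugt2b38 rose (1 higher and 2 lower adjusted over the list alone). Nop58, Rrs1, Pim3, Foxa2, Fmo2, Acot3, Slc16a5, Ugt2b38 and Cry2 were lost with each of the 4 libraries left out, Nop58 at an adjusted p of 0.095 to 0.106 and Rrs1 at 0.099 to 0.155. Foxa1 and Cebpb were kept only without the shallower Hypox library (adjusted p = 0.0126 and 0.00857). Of 19 clock genes tested Cry2 was called lower, with 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.000569, adjusted p = 0.196 with an estimated correlation). Gluconeogenesis and FOXO targets had 1 call, the fall of Igfbp1 among 16 tested, and 4 lower adjusted over the list alone (camera adjusted p = 0.000258, adjusted p = 0.357 with an estimated correlation). Camera called 8 of 22 pathway lists and 0 of 13 cell type lists. With an estimated correlation it called 0 of either kind, where the lowest adjusted p was 0.196 for pathways and 0.776 for cell types. Fry called 0 of either kind. Its adjusted p was 0.0971 for the GH and STAT5 list, 0.2 for ribosome biogenesis and 0.0989 for clock genes. Over all pathway lists 16 members were called higher and 3 lower, against 4 and 0 without the deeper Hypox library, 7 and 2 without the shallower Hypox library, 4 and 0 without the deeper 90 min library, and 5 and 0 without the shallower 90 min library.

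**Figure D2:**
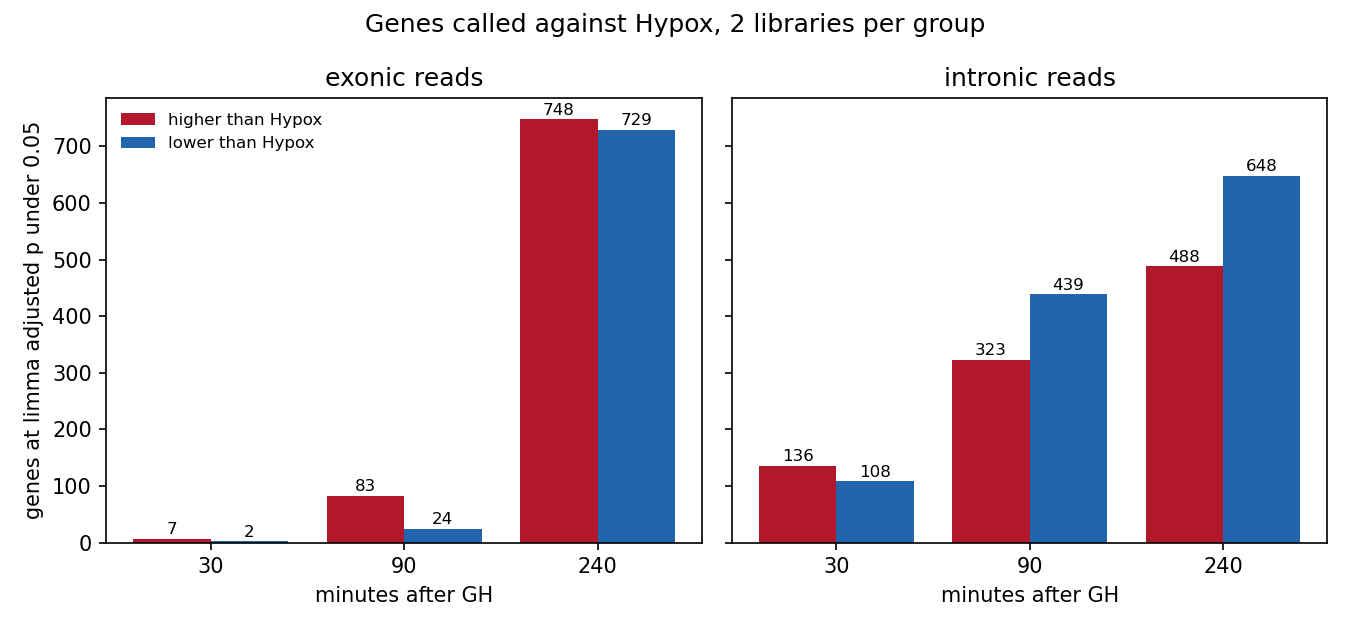
Genes called higher or lower than in Hypox by limma at an adjusted p under 0.05 (bars, number of genes) at 30, 90 and 240 min after GH, for exonic and for intronic reads. Exonic calls numbered 7 higher and 2 lower at 30 min and 748 higher and 729 lower at 240 min, whereas intronic calls numbered 136 higher and 108 lower at 30 min.

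At 240 min the growth mediator Igf1 and its carrier subunit gene Igfals had risen. Igf1 rose 4.26-fold (2.09 ± 0.27, adjusted p = 0.00228), from 43.1 and 49.5 CPM to 205 and 190 CPM. Igfals rose by 1.90 ± 0.23 (adjusted p = 0.00192). Socs2 and Cish were still 13.2-fold and 9.39-fold higher (adjusted p = 0.00433 and 0.00226), and Onecut1 was 9.86-fold higher (3.30 ± 0.21, adjusted p = 8.06e-05). The prolactin receptor gene Prlr rose by 1.11 ± 0.14 (adjusted p = 0.00228) and the GH receptor gene Ghr by 0.49 ± 0.12 (adjusted p = 0.0289). The call of Ghr was lost with each of the 4 libraries left out (adjusted p = 0.151 and 0.0703 without the deeper and shallower Hypox library, 0.0751 and 0.0778 without the deeper and shallower 240 min library) and with the groups fitted alone (0.0641). Bcl6, a repressor that competes with STAT5 for binding sites, was 6.78-fold lower (-2.76 ± 0.24, adjusted p = 0.000356), Socs3 4.12-fold lower (-2.04 ± 0.27, adjusted p = 0.00237). Stat5b fell by 0.88 ± 0.14 (adjusted p = 0.00487). Of 15 GH and STAT5 genes 5 rose and 3 fell (5 and 5 adjusted over the list alone), so that the list did not stand apart from the other genes (camera adjusted p = 0.385). In the GH receptor and IGF axis list 2 of 17 rose and 4 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.0261, adjusted p = 0.283 with an estimated correlation). Bcl6 lies on chromosome 16 from 23965138 to 23988698 in mm9. Alb, the main hepatocyte transcript, had a log2 fold change of -0.52 ± 0.27 (adjusted p = 0.24) and Cux2, a female-biased transcription factor gene, of -0.91 ± 0.55 (adjusted p = 0.321).

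Among genes with a mean of at least 2 CPM over both groups, the largest rises at 240 min were those of Ces2b (258 and 147 reads against 2 and 4), Nrep (25.7-fold, adjusted p = 0.000156), Socs2, Onecut1, Cish and Aacs (3.18 ± 0.24, adjusted p = 0.000156). They also included the potassium channel gene Kcnt2 (2.45 ± 0.49, adjusted p = 0.0129), the male-biased cytochrome P450 gene Cyp4a12b (2.40 ± 0.22, adjusted p = 0.000422) and Keg1. Another was that of Alas1, the rate-limiting enzyme of heme synthesis (2.12 ± 0.30, adjusted p = 0.00328). The falls included Fam13a (-2.77 ± 0.24, adjusted p = 0.000356), Ppp1r3g, a glycogen-targeting phosphatase subunit gene (-2.67 ± 0.32, adjusted p = 0.00165), and the neutrophil attractant gene Cxcl1, which was 5.61-fold lower (-2.49 ± 0.15, adjusted p = 8.06e-05). Cxcl1 lies on chromosome 5 from 91320271 to 91322141 in mm9. Limma called 748 genes higher and 729 lower, 215 and 212 of them at 2-fold or more, each with both treated libraries beyond both Hypox libraries, which held for 56.0% of all genes against 33.3% by chance. With library totals as the only scaling the split was 903 higher and 477 lower, 65.4% higher against 50.6%, and over all comparisons this scaling moved the median log2 fold change of all genes by at most 0.11. The authors' deposited table held 680 higher and 608 lower genes, and 1105 of the 1477 genes called here were in it in the same direction. The counts were 369 higher and 326 lower without the deeper Hypox library, 203 and 156 without the shallower Hypox library, 497 and 499 without the deeper 240 min library, and 326 and 440 without the shallower 240 min library. Of 109 named calls 50 were kept with each library left out, among them Igf1, Igfals, Socs2, Cish, Onecut1, Bcl6, Socs3, Stat5b, Prlr, Cxcl1, Fam13a, Ppp1r3g, Nrep, Aacs and Cyp4a12b. Of the others, 38 were lost without the deeper Hypox, 49 without the shallower Hypox, 30 without the deeper 240 min and 35 without the shallower 240 min library. Kcnt2 was lost without the shallower Hypox and the deeper 240 min library (adjusted p = 0.0933 and 0.0599). With the Hypox and 240 min groups fitted alone 461 genes were lower.

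Genes of ribosome biogenesis, endoplasmic reticulum stress, heat shock and cholesterol synthesis were among those that rose at 240 min. Of 29 ribosome biogenesis genes 20 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 1.02e-19, adjusted p = 0.157 with an estimated correlation, fry adjusted p = 0.00603). Nop58 was 3.58-fold higher (1.84 ± 0.16, adjusted p = 0.000356), and Tsr1 and Gnl3, which act in assembly of the small and large ribosomal subunits, rose by 1.34 ± 0.15 and 1.30 ± 0.15 (adjusted p = 0.00135 and 0.00143). Of 18 endoplasmic reticulum stress and ATF4 targets 13 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.37e-08, adjusted p = 0.0667 with an estimated correlation, fry adjusted p = 0.000755). The members that rose included Hspa5, which encodes the chaperone BiP (2.02-fold, 1.02 ± 0.12, adjusted p = 0.00138). Others were Dnajb9 (1.73 ± 0.19, adjusted p = 0.00135), Creld2 (1.73 ± 0.18, adjusted p = 0.000958) and Manf (1.59 ± 0.18, adjusted p = 0.00135). Of 12 heat shock genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 6.48e-06, adjusted p = 0.285 with an estimated correlation), including Hsp90aa1 (1.21 ± 0.17, adjusted p = 0.00271) and Bag3 (1.12 ± 0.17, adjusted p = 0.00455). Of 22 cholesterol synthesis genes 5 rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00706, adjusted p = 0.59 with an estimated correlation), with Sqle, which oxidizes squalene, at 1.23 ± 0.28 (adjusted p = 0.0214). Sqle was lost without the deeper Hypox and the shallower 240 min library (adjusted p = 0.122 and 0.11), and the other genes named here were kept with each library left out.

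Some chemokine, NF-kB target, immediate early and gluconeogenic genes fell at 240 min. Of 15 chemokines and NF-kB targets 9 fell and 0 rose (9 and 0 lower and higher adjusted over the list alone, camera adjusted p = 4.14e-08, adjusted p = 0.157 with an estimated correlation, fry adjusted p = 0.00603). Markers of cells that express such genes were lower beside them, with medians of -0.45 for Kupffer cells (camera adjusted p = 0.0394, adjusted p = 0.727 with an estimated correlation), -0.34 for sinusoidal endothelial cells (0.00658, adjusted p = 0.385 with an estimated correlation) and -0.78 for 4 neutrophil markers (0.12). The genes that fell included Il1b (-2.01 ± 0.22, adjusted p = 0.0013) and Icam1 (-0.85 ± 0.14, adjusted p = 0.0051). Of 24 immediate early genes 7 fell and 0 rose (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00507, adjusted p = 0.285 with an estimated correlation). Junb was at -2.03 ± 0.17 (adjusted p = 0.000326), Egr1 at -2.11 ± 0.42 (adjusted p = 0.0129) and Fos from 3.28 and 5.97 CPM to 1.23 and 0.863 CPM (adjusted p = 0.0253, and 0.0568 with limma-voom). Without the shallower Hypox library Egr1 (adjusted p = 0.0988), Fos (0.167) and Tat (0.0964) were lost, without the shallower 240 min library Egr1 (0.0816) and Fos (0.117), and without the deeper 240 min library Fos (0.0567) and Tat (0.0635). Of 16 gluconeogenesis and FOXO targets 6 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.00178, adjusted p = 0.359 with an estimated correlation). Among them were the coactivator gene Ppargc1a (-1.89 ± 0.36, adjusted p = 0.00978), the tyrosine aminotransferase gene Tat (-1.11 ± 0.23, adjusted p = 0.0139) and Igfbp1 (-2.32 ± 0.39, adjusted p = 0.00578). Pck1, the gene of a rate-limiting enzyme, had -0.67 ± 0.22 (adjusted p = 0.0733). Of 18 fatty acid synthesis genes 1 rose and 4 fell, among the latter the desaturase gene Scd1 (-1.43 ± 0.24, adjusted p = 0.00648), Gpam and Srebf1 (3 higher and 6 lower adjusted over the list alone). Srebf1 was lost without the deeper Hypox and the deeper 240 min library (adjusted p = 0.121 and 0.0938). Over all pathway lists 67 members were called higher and 51 lower, against 44 and 35 without the deeper Hypox library, 40 and 16 without the shallower Hypox library, 56 and 44 without the deeper 240 min library, and 45 and 28 without the shallower 240 min library. Camera called 10 of 22 pathway lists and 0 with an estimated correlation. Fry called 4, namely ribosome biogenesis, endoplasmic reticulum stress, chemokines and NF-kB targets, and the GH receptor and IGF axis. The fry adjusted p was 0.058 for each of the heat shock, immediate early and gluconeogenesis lists and 0.305 for cholesterol synthesis.

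**Figure D3:**
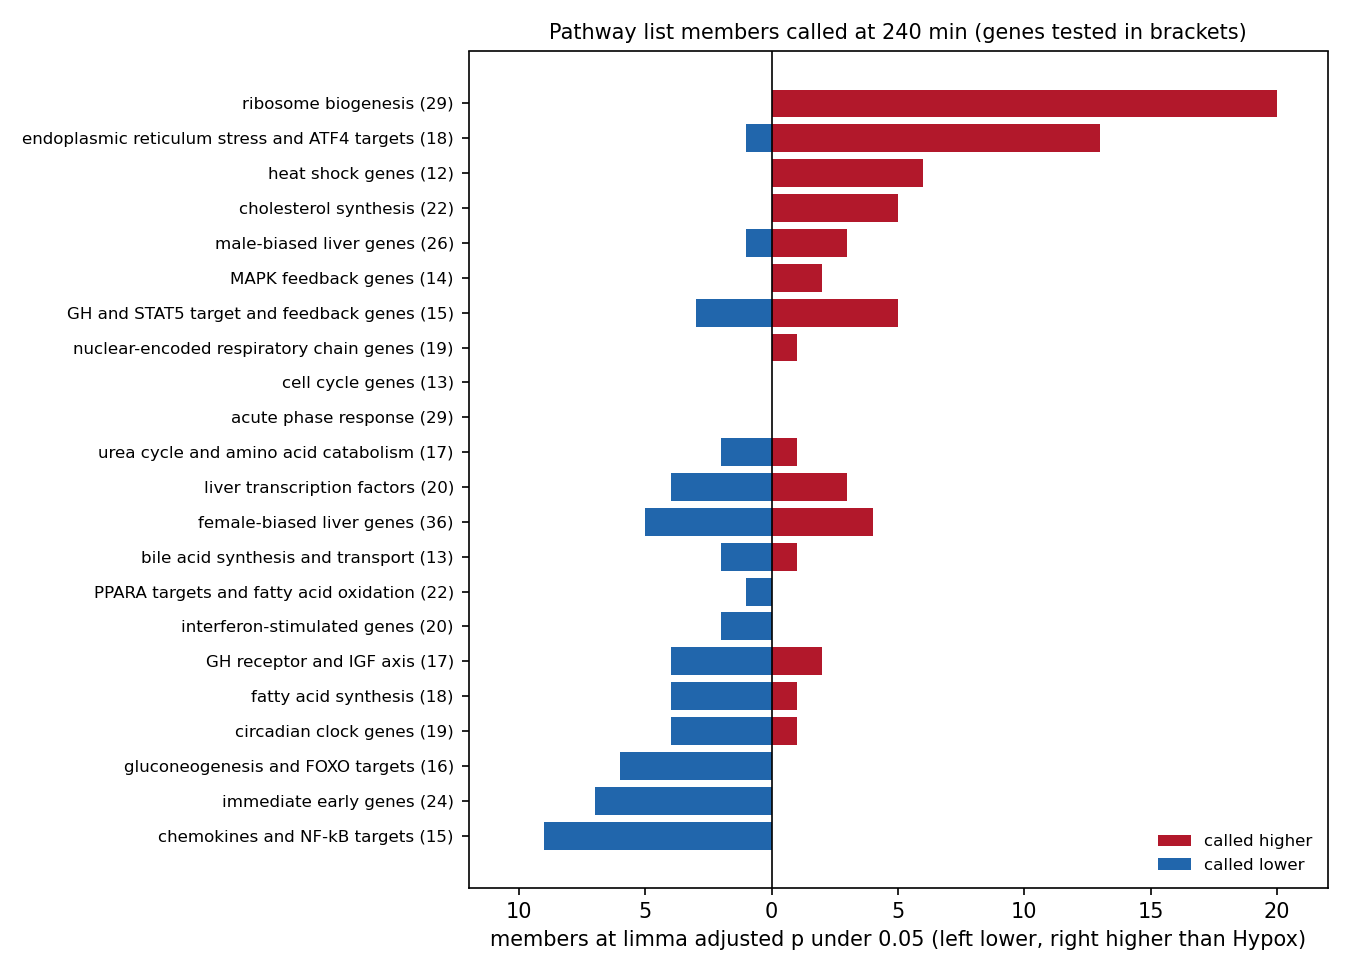
Members of the 22 pathway lists called lower (bars to the left) or higher (bars to the right) than in Hypox at 240 min by limma, in numbers of genes, with the number of genes tested in brackets. Ribosome biogenesis had 20 of 29 higher and chemokines and NF-kB targets 9 of 15 lower.

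Sex-biased genes, which respond to the pattern of GH secretion, moved in both directions at 240 min. Of 26 male-biased genes 3 rose, Cyp4a12a, Cyp4a12b and Ugt2b38, and Cyp2u1 fell (4 higher and 2 lower adjusted over the list alone). The list's median log2 fold change was -0.21 while its mean was 0.00. Of 36 female-biased genes 4 rose, among them Fmo2 (1.82 ± 0.27, adjusted p = 0.00389) and Trim24 (0.95 ± 0.15, adjusted p = 0.00517). Another 5 fell, among them Abcd2 (-0.95 ± 0.16, adjusted p = 0.00545), with 5 and 5 adjusted over the list alone. Of 20 liver transcription factors Foxa1, Foxa2 and Onecut2 rose and 4 fell, including the xenobiotic receptor gene Nr1i3, also named CAR (-1.45 ± 0.22, adjusted p = 0.004), and Nr5a2, with 5 and 5 adjusted over the list alone and a median of 0.01 beside a mean of -0.03. Of 19 clock genes 1 rose and 4 fell, the latter Per3 and the output regulators Dbp, Tef and Hlf (1 and 5 adjusted over the list alone). Of 13 bile acid genes the uptake transporter gene Slc10a1 rose (1.19 ± 0.16, adjusted p = 0.00269) and the export pump genes Abcb4 and Abcc2 fell (1 and 3 adjusted over the list alone). The fatty acid oxidation list had 1 fall of 22, Acaa1b (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.653 with an estimated correlation). The urea cycle and amino acid catabolism list had the rise of Oat and the falls of Arg1 and Tat of 17 (1 and 3 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.59 with an estimated correlation). Of 14 MAPK feedback genes Phlda1 and Errfi1 rose (2 higher and 1 lower adjusted over the list alone). At 90 min this list had a median of -0.05 and a mean of 0.12. Of 20 interferon-stimulated genes Mx2 and Usp18 fell (0 higher and 2 lower adjusted over the list alone). Of 19 respiratory chain genes Cycs rose (1 higher adjusted over the list alone). Fmo2, Trim24, Nr1i3, Slc10a1, Cyp4a12b, Ugt2b38, Phlda1 and Errfi1 were kept with each library left out. Without the shallower Hypox library the adjusted p was 0.0552 for Abcd2, 0.185 for Foxa2, 0.175 for Onecut2, 0.107 for Nr5a2, 0.0616 for Per3, 0.0844 for Dbp, 0.0501 for Tef, and 0.159 for Hlf. It was 0.0712 for Abcb4, 0.0663 for Abcc2, 0.173 for Arg1, 0.0964 for Tat, 0.23 for Oat, 0.11 for Cyp4a12a, 0.18 for Cyp2u1, 0.0686 for Mx2, 0.215 for Usp18 and 0.0721 for Cycs. Without the deeper Hypox library Foxa1 (0.134) and Acaa1b (0.0595) were lost, as were Tef (0.0573), Abcc2 (0.101), Cyp2u1 (0.133) and Cycs (0.115). Without the deeper 240 min library Hlf (0.109), Abcc2 (0.0942), Tat (0.0635), Cyp2u1 (0.175) and Cycs (0.0811) were lost, and without the shallower one Foxa1 (0.111), Onecut2 (0.118), Nr5a2 (0.071), Dbp (0.0519) and Arg1 (0.128). Cyp4a12a, Foxa2, Mx2, Usp18 and Oat were lost with each of the 4 libraries left out. Against Hypox, at any of the times, none of 29 acute phase genes or of 13 cell cycle genes was called by limma from exonic reads, over all genes or adjusted over the list alone. Between times 2 acute phase genes were lower at 240 than at 90 min and 1 lower at 240 than at 30 min. Adjusted over the list alone, 1 was higher at 90 than at 30 min.

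Markers of cell types other than hepatocytes also moved at 240 min. Of 7 tested cholangiocyte markers, which mark bile duct cells, 4 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.23, camera adjusted p = 0.0038, adjusted p = 0.584 with an estimated correlation). These were Krt19, at 0.259 and 0.251 CPM in Hypox and 0.817 and 2.27 CPM at 240 min, Krt7, Tspan8 and Spp1 (1.23 ± 0.27, adjusted p = 0.0173). Of 10 sinusoidal endothelial markers Stab2 (-0.64 ± 0.12, adjusted p = 0.0104) and Kdr fell (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00658, adjusted p = 0.385 with an estimated correlation, fry adjusted p = 0.00692). Kdr was lost with library totals alone (adjusted p = 0.113) and with the groups fitted alone (0.0912). Without the deeper Hypox library Krt19 (adjusted p = 0.106), Krt7 (0.237), Tspan8 (0.0848), Spp1 (0.103), Stab2 (0.0507), Kdr (0.108) and Oat (0.0676) were lost. Without the shallower Hypox library the lost genes were Krt19 (0.132), Krt7 (0.0973), Tspan8 (0.115), Stab2 (0.0669), Kdr (0.156), Arg1 (0.173) and Oat (0.23). Without the shallower 240 min library Krt19 (0.173), Spp1 (0.0985), Kdr (0.0835), Arg1 (0.128) and Oat (0.0511) were lost, and without the deeper one Kdr (0.0834) and Oat (0.154). Tspan8 and Krt7 had too few reads to be tested without either 240 min library. Kupffer cell markers had 0 of 10 called by limma (camera adjusted p = 0.0394, adjusted p = 0.727 with an estimated correlation). Periportal hepatocyte markers had 1 of 10 lower, Arg1, and 7 lower adjusted over the list alone (camera adjusted p = 0.0038, adjusted p = 0.584 with an estimated correlation), while pericentral markers had 1 of 10 higher, Oat, and the general hepatocyte markers 0 of 10. With 5 B cell, 5 T and NK cell, 4 neutrophil, 5 red blood cell, 2 adipocyte and 1 exocrine pancreas markers tested, the other lists rest on few genes.

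At 30 min limma called more genes from intronic than from exonic reads. Intronic reads of Igfbp1 were 20.6-fold lower at 30 min (adjusted p = 0.000182), those of Tat 11.8-fold and of Pck1 8.70-fold lower (adjusted p = 0.000116 for both). Exonic reads of Pck1 had a log2 fold change of -0.33 ± 0.22 (adjusted p = 0.841). Intronic reads of Onecut1 (2.97, adjusted p = 0.000116), Cish (3.39, adjusted p = 0.00509) and Myc (3.26, adjusted p = 0.00245) were higher at 30 min. Limma called 136 genes higher and 108 lower of 10164 from intronic reads at 30 min, 323 and 439 at 90 min, and 488 and 648 at 240 min. The authors' deposited table held 214 and 234, 511 and 747, and 584 and 877 intronic calls. Of 134 genes with an intronic rise at 30 min that were also tested in exons, 5 had an exonic rise called at 30 min, 39 at 90 min and 57 at 240 min. Of 106 with an intronic fall 1, 4 and 43 had an exonic fall called, and 3 an exonic rise at 240 min. Over all 13169 genes exonic rises numbered 7, 83 and 748 and falls 2, 24 and 729. Median exonic log2 fold changes were 0.34, 0.7 and 0.59 for the intronic rises and -0.25, -0.29 and -0.53 for the falls. Both kinds of reads share the Hypox libraries, and no unchanged groups were simulated for these overlaps. Without the deeper Hypox, shallower Hypox, deeper 30 min or shallower 30 min library the 30 min intronic counts were 43, 65, 189 and 62 higher and 46, 34, 165 and 52 lower. The counts at 90 min without the deeper Hypox, shallower Hypox, deeper 90 min or shallower 90 min library were 182, 145, 175 and 123 higher and 263, 148, 281 and 193 lower. At 240 min they were 431, 35, 76 and 179 higher and 513, 105, 168 and 339 lower, in the same order of libraries. With each library left out, the intronic calls of Cish, Igfbp1, Myc, Onecut1, Pck1 and Tat at 30 min were kept. Pck1 lies on chromosome 2 from 172978574 to 172984754 in mm9.

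Intronic reads of amino acid catabolism, gluconeogenesis and the acute phase response fell. Of 17 urea cycle and amino acid catabolism genes 6 were lower at 30 min, 10 at 90 min and 5 at 240 min, none higher (10, 14 and 7 lower adjusted over the list alone), with medians of -0.78, -1.01 and -0.52. Arg1, which makes urea, was at -1.96 at 90 min (adjusted p = 0.000248). At 90 min the camera adjusted p of this list was 6.55e-13 (adjusted p = 0.161 with an estimated correlation). Markers of both zones of hepatocytes moved with it. Periportal markers, which share Arg1 and 5 other genes with that list, had 4, 7 and 1 of 9 lower (7, 9 and 1 adjusted over the list alone), and pericentral markers, which share Oat, 1, 4 and 3 of 8 (3, 6 and 4 adjusted over the list alone). Their medians at 90 min were -1.96 (camera adjusted p = 2.97e-12, adjusted p = 0.12 with an estimated correlation) and -1.34 (5.77e-05, adjusted p = 0.12 with an estimated correlation). Of 14 gluconeogenesis and FOXO targets 5, 8 and 6 were lower (10, 9 and 8 adjusted over the list alone). Ribosome biogenesis introns were higher in 8 of 25 genes at 90 min and 9 at 240 min (15 and 16 adjusted over the list alone), and those of endoplasmic reticulum stress genes in 10 of 18 at 240 min (11 adjusted over the list alone). At 240 min 17 of 24 acute phase genes were lower in introns and 0 higher (21 lower adjusted over the list alone, median -1.72, camera adjusted p = 1.07e-15, adjusted p = 0.338 with an estimated correlation). Saa1, Hp and Fgb, looked at after their values were seen, had intronic log2 fold changes of -4.60, -2.49 and -1.49 at 240 min (adjusted p = 0.000424, 0.00173 and 0.00354). Their exonic values were -0.40 ± 0.64, -0.39 ± 0.22 and 0.57 ± 0.36 (adjusted p = 0.735, 0.291 and 0.345). Without the shallower Hypox library the intronic call of Fgb was lost (adjusted p = 0.0528). Saa1 lies on chromosome 7 from 53995869 to 53998350 in mm9.

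**Figure D4:**
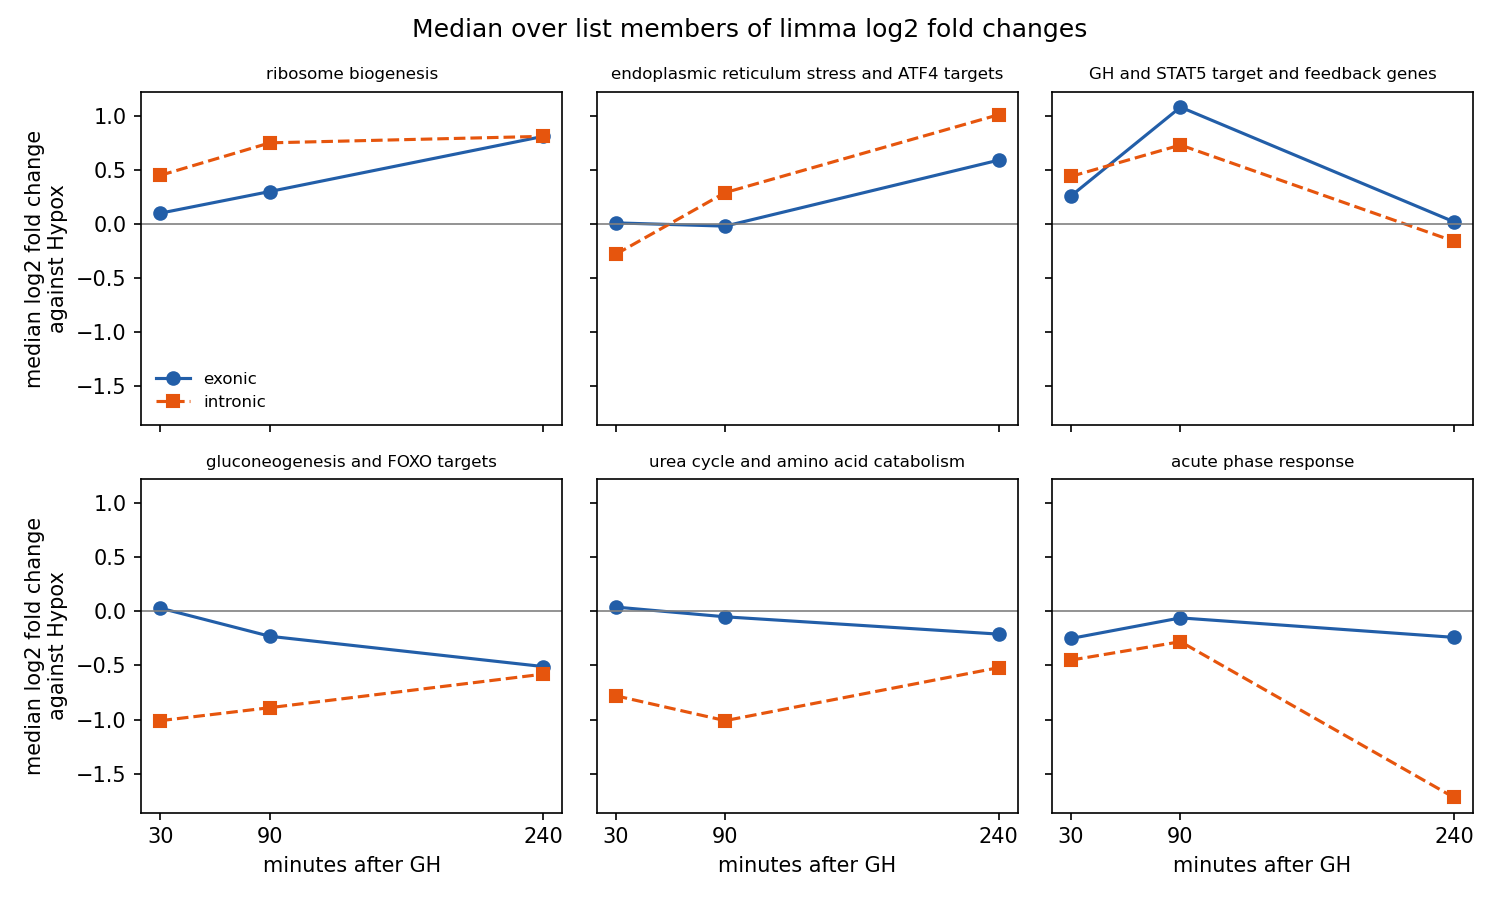
Median limma log2 fold change against Hypox (vertical axis) of 6 pathway lists at 30, 90 and 240 min after GH (horizontal axis), with solid lines and circles for exonic and dashed lines and squares for intronic reads. For gluconeogenesis and FOXO targets the intronic median was -1.01 at 30 min beside an exonic median of 0.03, and for the acute phase response the intronic median was -1.72 at 240 min beside an exonic median of -0.24.

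The differences between times were tested directly. Between 90 and 240 min Arid5a fell by 3.14 ± 0.34 (adjusted p = 0.00229), Socs1 by 2.88 ± 0.45 (0.00852), Cxcl1 by 2.84 ± 0.15 (2.68e-05), Socs3 by 2.60 ± 0.27 (0.00201) and Myc by 2.15 ± 0.33 (0.00795). Over the same interval G0s2 rose by 2.92 ± 0.35 (adjusted p = 0.00315) and Gm6484 by 2.73 ± 0.37 (0.00499). Endoplasmic reticulum stress and ATF4 targets rose in 11 of 18 genes (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.39e-11), a call that was kept when the correlation was estimated (adjusted p = 0.0363). Ribosome biogenesis genes rose in 8 of 29 (21 adjusted over the list alone, camera adjusted p = 1.2e-12, adjusted p = 0.259 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 22 (12 adjusted over the list alone, camera adjusted p = 2.37e-08, adjusted p = 0.259 with an estimated correlation). The GH and STAT5 list had 6 of 15 lower (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.365 with an estimated correlation). Limma called 363 genes higher and 325 lower at 240 than at 90 min. The counts were 75 and 64 without the deeper 90 min library, 55 and 45 without the shallower 90 min library, 270 and 310 without the deeper 240 min library, and 74 and 113 without the shallower 240 min library. The named falls of Arid5a, Cxcl1 and Socs3 and the rise of G0s2 were kept with each of these left out, while Socs1 (adjusted p = 0.0719) and Myc (0.074) were lost without the deeper 90 min library and Gm6484 (0.0507) without the shallower 90 min library.

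Between 30 and 240 min Egr1 fell by 2.95 ± 0.42 (adjusted p = 0.00419), Fam13a by 2.90 ± 0.24 (0.000695) and Cxcl1 by 2.58 ± 0.15 (7.15e-05). Over this interval Kcnt2, Nrep and the EGF receptor gene Egfr rose (adjusted p = 0.0102, 0.00385 and 0.0154), Kcnt2 by 2.67 ± 0.49 and Egfr by 2.18 ± 0.45. Ribosome biogenesis genes rose in 18 of 29 (23 adjusted over the list alone, camera adjusted p = 2.41e-17, adjusted p = 0.207 with an estimated correlation). In turn, fatty acid synthesis genes fell in 6 of 18 (11 adjusted over the list alone, camera adjusted p = 1e-04, adjusted p = 0.207 with an estimated correlation). Limma called 618 genes higher and 662 lower, or 909 and 372 with library totals as the only scaling, 71.0% higher against 48.3%. The counts were 215 and 243 without the deeper 30 min library, 295 and 259 without the shallower 30 min library, 443 and 532 without the deeper 240 min library, and 192 and 274 without the shallower 240 min library. With the 30 and 240 min groups fitted alone they were 351 and 342, and Egfr was lost without the deeper 30 min and the shallower 240 min library (adjusted p = 0.0689 and 0.0959).

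Between 30 and 90 min limma called 0 genes in either direction, with 1161 of 13169 genes at an unadjusted p under 0.05. Limma-voom called 1 gene higher and 0 lower, library totals alone 7 and 0, and the groups fitted alone 0 and 0. Chemokines and NF-kB targets were higher at 90 than at 30 min as a group (camera adjusted p = 4.6e-11, adjusted p = 0.0904 with an estimated correlation, fry adjusted p = 0.0404). Neutrophil markers moved with them (camera adjusted p = 6.94e-05, adjusted p = 0.594 with an estimated correlation). Fatty acid synthesis genes were lower (camera adjusted p = 1.03e-10, adjusted p = 0.0904 with an estimated correlation, fry adjusted p = 0.0404). Without the shallower 30 min library 23 genes were higher and 9 lower, and without the deeper 30 min library 1 and 12.

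Genes were grouped by the tests between times as well as against Hypox. In 23 genes a rise at 30 or 90 min was followed by a fall to 240 min, among them Myc, Phlda1, Fzd4, Fzd7, Socs1, Arid5a, Sybu, Pim3 and, chosen after its values were seen, Gadd45g. The 90 min rises of Fzd4, Fzd7, Socs1, Arid5a, Sybu, Pim3 and Gadd45g were not kept in every fit with a library left out. Nor were the falls of Myc and Socs1 from 90 to 240 min. In 5 genes, Fzd5, G0s2, Icam1, Ppp1r3c and Zfp750, a fall at 30 or 90 min was followed by a rise from that time to 240 min. Icam1 did not rise steadily, with deposited mean FPKM of 5.49 in Hypox and 2.03, 4.61 and 3.18 at 30, 90 and 240 min. The 90 min falls of G0s2 and Ppp1r3c were lost with each library left out. Another 453 genes were classed as late rises, with a call at 240 min and between 30 and 240 min but not at 30 min. By the same rule 428 were classed as late falls. The rule did not use the 90 min calls, so these classes can hold genes already called at 90 min, such as Nrep. A gene not called at 30 min may also have changed by then. A rise called at all 3 times was found for Aacs, Ces2b, Onecut1 and Phlda1, and limma gave 0 such falls (1 with limma-voom). The 90 and 240 min lists shared 50 rises and 11 falls, against 4.71 and 1.33 for independent lists and 36.3 and 12.6 in simulated unchanged groups set against the same Hypox libraries. The 30 and 90 min lists shared 7 rises and 0 falls, against 0.0441 and 0.00364 for independent lists and 1.63 and 0.36 simulated. The 30 and 240 min lists shared 4 rises and 2 falls, against 0.398 and 0.111 and simulated 4.35 and 1.47. The simulated lists were the top-ranked genes at the lengths of the called lists, with no threshold on the adjusted p. Called lists need not overlap as those did, so the simulation cannot decide how much of an overlap the shared libraries gave. The observed number was below the simulated one for the falls shared by 90 and 240 min and by 30 and 90 min. It was also below for the rises shared by 30 and 240 min, and above it for those shared by 90 and 240 min. Any excess over the simulated numbers may also come in part from the shared Hypox libraries, which are too few to be split.

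Of 734 tested non-coding genes, those whose listed transcripts are all non-coding, some were called at 90 and 240 min. Over all 13169 genes tested, 83 rose and 24 fell at 90 min, and 748 rose and 729 fell at 240 min. At 90 min 4 non-coding genes rose, including 1810064F22Rik (1.62 ± 0.26, adjusted p = 0.0218). Another 4 fell, including the small nucleolar RNA genes Snora81 (-1.70 ± 0.33, adjusted p = 0.0495) and Snora23 (-1.60 ± 0.24, adjusted p = 0.0157). At 240 min 10 rose and 34 fell, with the small nucleolar RNA host gene Snhg1 at 1.14 ± 0.28 (adjusted p = 0.03) and 4931408D14Rik at -2.12 ± 0.23 (adjusted p = 0.00114). At 30 min limma called 0 in either direction, against 1 higher with limma-voom and 1 higher with a pseudocount of 1. Snora81 and Snora23 were lost with each of the 4 libraries left out (adjusted p = 0.176 to 0.322 and 0.0804 to 0.143). At 90 min 1810064F22Rik was lost without the deeper Hypox, deeper 90 min and shallower 90 min library (adjusted p = 0.095, 0.0708 and 0.237). Snhg1 was lost without the shallower Hypox, deeper 240 min and shallower 240 min library (0.193, 0.0952 and 0.0959) and without a filter on low reads (0.0566), while 4931408D14Rik was kept in all 4 cases.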

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

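The differences between times described here were planned comparisons, while Fzd4 and Depdc7 were chosen after their values were seen. Fzd4, a receptor for Wnt ligands and for norrin, went in opposite directions early and late after GH. Its exonic CPM was 9.71 and 9.65 in the Hypox libraries, 19 and 19.8 at 30 min, 20.1 and 18.5 at 90 min, and 5.01 and 5.36 at 240 min. Fzd4 rose at 30 min (log2 fold change 1.00 ± 0.12, adjusted p = 0.0171) and at 90 min (0.99 ± 0.12, adjusted p = 0.00923) and fell below Hypox at 240 min (-0.89 ± 0.12, adjusted p = 0.00284). By limma the difference was -1.88 between 240 and 30 min (SE 0.12, adjusted p = 0.000108) and -1.88 between 240 and 90 min (adjusted p = 0.000112). Both differences and the fall at 240 min were called with each library of their groups left out. The rise at 30 min was lost without the deeper Hypox, shallower Hypox and shallower 30 min library (adjusted p = 0.157, 0.0823 and 0.133). The rise at 90 min was lost without the deeper Hypox, shallower Hypox, deeper 90 min and shallower 90 min library (adjusted p = 0.0915, 0.053, 0.0708 and 0.0742). Fzd4 lies on chromosome 7 from 96552876 to 96558620 in mm9.

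Depdc7, a gene with a DEP domain, a fold found in several signalling proteins, also reversed. Its exonic CPM was 13.2 and 15.1 in Hypox, 17.3 and 19.3 at 30 min, 25.4 and 31.2 at 90 min, and 8.39 and 9 at 240 min. Depdc7 rose at 90 min (0.99 ± 0.14, adjusted p = 0.0131) and fell below Hypox at 240 min (-0.70 ± 0.14, adjusted p = 0.0135). By limma the difference between 240 and 90 min was -1.69 ± 0.14 (adjusted p = 0.000903), and it was called with each library of its groups left out. The rise at 90 min was lost without the deeper Hypox, shallower Hypox, deeper 90 min and shallower 90 min library (adjusted p = 0.103, 0.053, 0.0514 and 0.159), and the fall at 240 min without the shallower Hypox and the deeper 240 min library (0.1 and 0.0531). Depdc7 lies on chromosome 2 from 104561944 to 104582958 in mm9.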

How the results depend on the processing

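The settings with the groups fitted alone, the authors' deposited adjusted p, intronic reads and the estimated correlation were added after results had been seen. The counts against Hypox, given as higher and lower genes, were 7 and 2 at 30 min, 83 and 24 at 90 min and 748 and 729 at 240 min, and between times 0 and 0 from 30 to 90 min, 363 and 325 from 90 to 240 min and 618 and 662 from 30 to 240 min. Camera called 14, 8 and 10 pathway lists and 2, 0 and 4 cell type lists at 30, 90 and 240 min. Pathway list members called higher and lower were 3 and 2, 16 and 3, and 67 and 51. No call of a named gene turned direction. The balance of higher and lower calls turned under several settings, including library totals alone (from 48.3% to 71.0% higher from 30 to 240 min), the groups fitted alone, the authors' deposited adjusted p, intronic reads and some fits with a library left out. The cause of the changes was not tested except where a setting by construction removes calls.

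With the 2 groups of a comparison fitted alone, genes at 30 min were 3 higher and 4 lower, lower genes were 54 at 90 min and 461 at 240 min, and from 30 to 240 min 351 were higher and 342 lower. Pathway members lower at 90 min were 11. A log2 fold change of at least 1 in size, which can only remove calls, left 55 and 12 at 90 min, 215 and 212 at 240 min, 131 and 111 from 90 to 240 min, 190 and 191 from 30 to 240 min, and 36 and 23 pathway members at 240 min. By the adjusted p of the authors' deposited table, 46 and 59 genes were called at 30 min and 221 and 166 at 90 min. With library totals alone, 477 genes were lower at 240 min, 7 were higher from 30 to 90 min and 372 lower from 30 to 240 min. The sustained rises then went from 4 to 8, the late falls from 428 to 247, and the intronic falls at 30 min from 108 to 176.

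With intronic reads 136 and 108 genes were called at 30 min, 323 and 439 at 90 min, 488 higher at 240 min, and 550 and 590 from 90 to 240 min. Cell type lists called were 2 at 90 min and 0 at 240 min, and pathway members 19 and 21 at 30 min, 32 and 49 at 90 min and 31 higher at 240 min. With an estimated correlation camera called 0 pathway lists at 30 min, 0 at 90 min and 0 at 240 min, and 0 cell type lists at 30 and 0 at 240 min. Requiring 1 CPM in 2 libraries gave 2 cell type lists at 240 min and, of non-coding genes at 90 min, 1 higher and 2 lower in place of 4 and 4. Limma-voom gave 1 gene higher from 30 to 90 min, 1 cell type list at 90 min and 1 pathway member lower at 30 min. It gave 2 sustained rises, 2 genes that returned after a fall in place of 5, 1 sustained fall in place of 0, and 1 non-coding gene higher at 30 min in place of 0. Without a filter 1 gene was lower at 30 min, 53 were higher and 12 lower at 90 min, and 1 higher and 1 lower from 30 to 90 min. Cell type lists were then 1 at 30 min and 1 at 90 min, pathway members lower 1 at 30 min and 1 at 90 min, and genes that returned after a fall 3. A pseudocount of 1 gave 2 higher and 1 lower from 30 to 90 min and 1 non-coding gene higher at 30 min.

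Leaving out 1 library at a time leaves a lone library that is assumed to vary like the other groups. The lowest and highest counts of genes higher were 1 and 30 at 30 min, 8 and 18 at 90 min, 203 and 497 at 240 min, 0 and 23 from 30 to 90 min, 55 and 270 from 90 to 240 min, and 192 and 443 from 30 to 240 min. Those of genes lower were 0 and 8, 0 and 5, 156 and 499, 0 and 12, 45 and 310, and 243 and 532, in the same order. Pathway members higher ranged from 1 to 12, 4 to 7 and 40 to 56 at 30, 90 and 240 min, and lower from 0 to 5, 0 to 2 and 16 to 44. Intronic genes higher ranged from 43 to 189, 123 to 182 and 35 to 431, and lower from 34 to 165, 148 to 281 and 105 to 513.

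Over the 330 calls of named genes, 3481 values from other settings held 2840 of the same call, 641 weaker ones and 0 reversed, and 515 of the weaker ones came from leaving out a library. No paired analysis was possible because the recovered libraries carry no pool number, so that pools of different groups could not be matched. The planned edgeR tests, DESeq2, its size factors and the replicate block were not run, and the camera tests were not repeated with libraries left out. With 2 libraries per group and 15.9 to 34.5 M mapped reads, genes with few reads could be called only at large changes.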

Other observations

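Foxq1, Zfp217 and Id1 were chosen after their values were seen, while the differences between times were planned comparisons. Foxq1, a forkhead transcription factor gene, had a log2 fold change of 1.04 at 90 min (adjusted p = 0.169) and fell at 240 min (-1.39, adjusted p = 0.0135), with a limma difference between the times of -2.42 ± 0.28 (adjusted p = 0.00311). Zfp217, a zinc finger gene, went the same way, at 0.76 (adjusted p = 0.21) and -0.79 (0.0447), with a difference of -1.55 ± 0.22 (0.00573). Id1, an inhibitor of basic helix-loop-helix factors, was at -1.32 (adjusted p = 0.285) and 0.92 (0.196) and rose between 90 and 240 min by 2.24 ± 0.43 (0.0181). Nr0b2, the bile acid responsive repressor SHP, was at -1.54 at 90 min (adjusted p = 0.0551) and rose by 2.13 ± 0.31 between 90 and 240 min (0.00597). With libraries left out, the difference between 90 and 240 min was kept in all 4 cases for Foxq1, lost without the shallower 90 min library for Zfp217 (adjusted p = 0.0559), lost without the deeper 90 min library for Nr0b2 (0.0547), and lost without the shallower 90 min, deeper 240 min and shallower 240 min library for Id1 (0.133, 0.0794 and 0.0529). The fall at 240 min against Hypox was lost without the deeper Hypox and shallower 240 min library for Foxq1 (0.0873 and 0.0673), and without the deeper Hypox, shallower Hypox and deeper 240 min library for Zfp217 (0.0935, 0.221 and 0.201) or without a filter (0.069). Intronic reads of the urea cycle and amino acid catabolism list, lower at 90 min, rose again by 240 min in 6 of 17 genes (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00224, adjusted p = 0.582 with an estimated correlation). So did those of 5 of 9 periportal hepatocyte markers (7 adjusted over the list alone, camera adjusted p = 1.23e-07, adjusted p = 0.443 with an estimated correlation) and of 2 of 8 pericentral markers (5 adjusted over the list alone, median 0.68, camera adjusted p = 0.0703).

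The tests in the following paragraphs were all chosen only after the result was seen. Lars2 encodes the mitochondrial leucyl-tRNA synthetase, and its exonic reads differed 17.9-fold between the 2 libraries at 30 min. Those of Mir6236 stood at 42.6 and 281 CPM before scaling. Both were called higher at 30 min by the authors' deposited adjusted p, Lars2 at 173-fold (2.07e-09) and Mir6236 at 450-fold (5.17e-20). At 240 min the authors' deposited values were 26.3-fold (3.8e-06) and 118-fold (1.63e-06). Ribosomal RNA left after depletion could be counted at these genes, and Lars2 had Spearman's rho 0.67 with Rn45s over 8 libraries (exact p = 0.0831). Pearson's r was 0.82 and 0.07 without the 2 farthest libraries, so the relation rests on those and stays open. Intronic reads of Lars2 at 30 min had a log2 fold change of 0.01, with 95% limits of -0.47 and 0.48. A rise in transcription as large as the exonic 6.19 ± 1.33 (adjusted p = 0.236) was thus excluded, while a GH effect within those limits was not.

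Male-biased genes were more abundant in the shallower than in the deeper library, with a median difference over 26 genes of 0.57 in Hypox, 1.01 at 30 min, 0.04 at 90 min and 0.32 at 240 min. Reads carried over from the shallower 30 min library could explain the Hypox difference, but the share needed by 5 of these genes, 26.9%, would have brought 12098 Lars2 reads, and 227 were observed. Some GH left in the mice of the shallower Hypox pool might be the source, and the GH and STAT5 list stood at percentile 100 of 10000 matched lists in the difference between the Hypox libraries (median 0.25). The GH and STAT5 list also stood at percentile 100 between the 30 min libraries (median 0.59), whose pools were both given GH. Against Hypox the male-biased list had a median of 0.19 at 30 min (camera adjusted p = 0.00602, adjusted p = 0.614 with an estimated correlation). Its medians were -0.27 at 90 min and -0.21 at 240 min. The percentile between the Hypox libraries therefore fits residual GH without setting it apart from another difference between pools, and the source stays open.

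Intronic reads of acute phase genes, which encode plasma proteins made in inflammation, fell at 240 min against Hypox while exonic reads were not called in that comparison. A shift of all intronic reads was excluded, as the list lay -1.71 from the other genes. Of 24 members, 23 had 50 or more intronic reads in each Hypox library, and 17 of these (73.9%) were called lower. The calls thus did not rest on members with few Hypox reads. As nearly all members passed this filter, the share called was almost fixed in advance and tests the explanation no further. Reduced transcription not yet fully seen in long-lived mRNA may be the reason. The exonic median of the 17 members with a called intronic fall, -0.24, lay at percentile 2.4 of 10000 matched lists. This is right at the bound of 2.5 set for it. The members were picked by a fall in the same libraries and the matched lists were not, so the percentile cannot decide. The reading is a hypothesis only.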
